A study of Mus musculus with 4 samples.

How the data were processed

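RNA from primary mouse embryonic fibroblasts, connective tissue cells grown directly from embryos, was measured on Affymetrix 1-colour oligonucleotide arrays with biotin-labelled RNA, per the labels. The labels name 2 independent lines of wild-type cells and 2 of cells that lack RBP2, all at passage 3, with 1 array per line. RBP2 stands for retinoblastoma binding protein 2, the lysine demethylase whose current gene symbol is Kdm5a, and not for retinol binding protein. Replicate numbers are those of the sample titles, and no litter, day or batch is stated for them. With 2 lines per genotype, p-values measure only the spread between these lines, and the number of arrays limits the precision of every value. An exact two-sided permutation test of 2 lines against 2 cannot give a p below 0.333, so the tests pool the spread over all probe sets.

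The deposited table holds 1 linear signal intensity per probe set and array, for 45101 probe sets of which 64 are Affymetrix controls. A probe set is a group of short probes meant to read 1 transcript, although some can bind several. How probes were summarised, whether background was corrected and which probe sets were called present is not given in the sources used here. The trimmed mean of the deposited intensity, leaving out 2% at each end, was 61.7 and 101 in wild-type replicates 1 and 2, and 78.0 and 152 in RBP2-null replicates 1 and 2. The largest was 2.46 times the smallest, so the arrays had not been brought to a common level. No pair of arrays held identical values.

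The following choices were made before the data were examined. Arrays whose trimmed means lay within 10% were to be used as deposited and otherwise quantile normalized, and the observed ratio led to quantile normalization of the linear values. A pseudocount of 9, the 25th percentile of all values rounded to a whole number, was added before taking log2, so fold changes are on the log2(signal + 9) scale and understate the change of dim probe sets. Control probe sets were left out, and the upper 60% of the others by mean over all 4 arrays were kept, which left 27022. RBP2-null was compared with wild type in limma 3.58.1 under R 4.3.3, with lmFit and with eBayes using a mean-dependent prior variance. Tests were two-sided, p-values were adjusted by the Benjamini-Hochberg method over all kept probe sets, and the threshold was an adjusted p of 0.05. Intervals are 95% intervals from the same fit.

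Gene names came from a platform annotation table, which gave 1 symbol for 34945 of the 45037 probe sets that are not controls, several for 932 and none for 9160, and probe sets with several symbols were not named. The Entrez gene numbers of 34741 probe sets matched a RefSeq gene table of assembly GRCm38.p6, which served only for names and for which genes neighbour each other. The 23001 kept probe sets with 1 symbol covered 13097 genes. For gene lists, their members, the KDM5 family, Cxcl12 and Kitl, the probe set of a gene with the highest mean over all 4 arrays was used. Genes named for a small p are given on the probe set with that p, which is not always the brightest.

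A set of 32 gene lists was fixed, covering histone enzymes, cell cycle, metabolism, stress, matrix and markers of other cell types, and including the 40 measured genes on either side of Kdm5a. Of the 988 distinct symbols in the lists that had been written out by name, 903 had a named probe set. Lists with at least 5 measured genes were tested with camera in limma, with a preset inter-gene correlation of 0.01, and beside it with camera using an estimated correlation and with fry. The genes named are the KDM5 family, Cxcl12 and Kitl, then the 12 with the largest rise and the 12 with the largest fall among those past the threshold whose RBP2-null arrays both lay beyond both wild-type arrays. Where fewer passed, genes with an absolute log2 fold change of at least 1 followed in order of unadjusted p, as values and not as calls. Up to 4 members of each list with the smallest unadjusted p were also named.

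The procedure was tested on simulated arrays with the real means, with a spread drawn from the fitted prior and with unequal brightness. In 10 runs with 200 changed probe sets each among 27022, it called 1.27% of the log2 changes of 1, 31% of those of 2 and 62.5% of those of 3. Of 646 calls, 38 were false, or 5.88%. A simulated list of 40 genes shifted by 0.4 was found by camera in the right direction, and 2 of 100 unshifted lists had an unadjusted p under 0.05. Genes and arrays were simulated as independent, so these rates do not cover correlated genes or differences shared by some lines. In the real data the estimated correlation within a list reached 0.55, that of smooth muscle genes. Alternatives covered the pseudocount, the filter, the scaling, the variance model, probe sets that can bind several transcripts, the replicate number as a block, the threshold, the list test, each array left out in turn, and the sex of the lines, with the list test also run with an estimated correlation in the settings where lists passed. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.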

Results

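Expression profiles were obtained from 4 lines of primary mouse embryonic fibroblasts at passage 3, of which 2 were wild type and 2 lacked RBP2. RBP2, encoded by Kdm5a, removes methyl groups from lysine 4 of histone H3, a mark of active promoters. The comparison asks which transcripts differ in level when this enzyme is absent. Median deposited signal was 22.7 and 29.4 in wild-type replicates 1 and 2 and 21.5 and 43.7 in RBP2-null replicates 1 and 2. The ratio of 3' to 5' signal of the Actb control, a measure of RNA integrity, lay between 1.02 and 1.14 on the 4 arrays. After normalization, the correlation across probe sets between arrays was 0.929, 0.927 and 0.927 for wild-type replicate 1 with the other arrays. Among those other arrays it was 0.951, 0.965 and 0.948, so wild-type replicate 1 stood apart. The deposited signal of the added controls BioB and cre was also lowest on that array, at 150.5 and 6698. On the other arrays BioB had 303.6, 279.1 and 393.4, and cre had 10496, 10250 and 11575. Whether the array or the line set this replicate apart was not tested.

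Cxcl12, a chemokine that attracts haematopoietic and other cells through the receptor Cxcr4, was higher in both RBP2-null lines than in both wild-type lines. Its brightest probe set had a normalized log2 signal of 7.84 ± 0.31 (SD, n = 2) in wild type and 10.64 ± 0.19 (SD, n = 2) in RBP2-null cells. The log2 fold change of Cxcl12 was 2.79 with a standard error of 0.23 and a 95% interval from 2.27 to 3.32, or 6.93-fold, with a limma adjusted p of 0.0316. Another Cxcl12 probe set had a log2 fold change of 2.58 with a standard error of 0.30 but did not pass the threshold, with an adjusted p of 0.225. As deposited, the signal of the brightest Cxcl12 probe set was 157.5 and 195.6 in the wild-type lines and 1227 and 2552 in the RBP2-null lines. A further Cxcl12 probe set was too dim to be kept. Cxcl12 lost its call with an adjusted p of 0.0873 without RBP2-null replicate 2, 0.484 without scaling, 0.115 without the filter, 1 without the mean-dependent variance and 0.0703 with the sex of the lines in the fit.

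The 1 probe set of Cxcl12 was the only one of 27022 past the threshold, with 1 higher and 0 lower in RBP2-null cells. At an unadjusted p under 0.05 there were 805 probe sets, 422 higher and 383 lower, where 1351 would be reached by chance alone. The 2 RBP2-null arrays lay on the same side of both wild-type arrays for 7969 probe sets, or 29.5%, against 33.3% by chance. Splitting the same arrays by replicate number gave 2541 probe sets at an unadjusted limma p under 0.05. Such a difference adds to the spread within genotypes, so the counts below chance do not show that genotype had no effect. The median standard error of a log2 fold change was 0.33. The count depended on wild-type replicate 2, without which 42 probe sets passed, 39 higher and 3 lower, and it was 2 without wild-type replicate 1, 2 with median-centred arrays and 0 without RBP2-null replicate 2. It was also 0 without the filter, without scaling, without the mean-dependent variance and with the sex of the lines in the fit. With the replicate number as a block the count was higher, and it is given below with the reason the numbers were not taken as pairs.

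**Figure D1:**
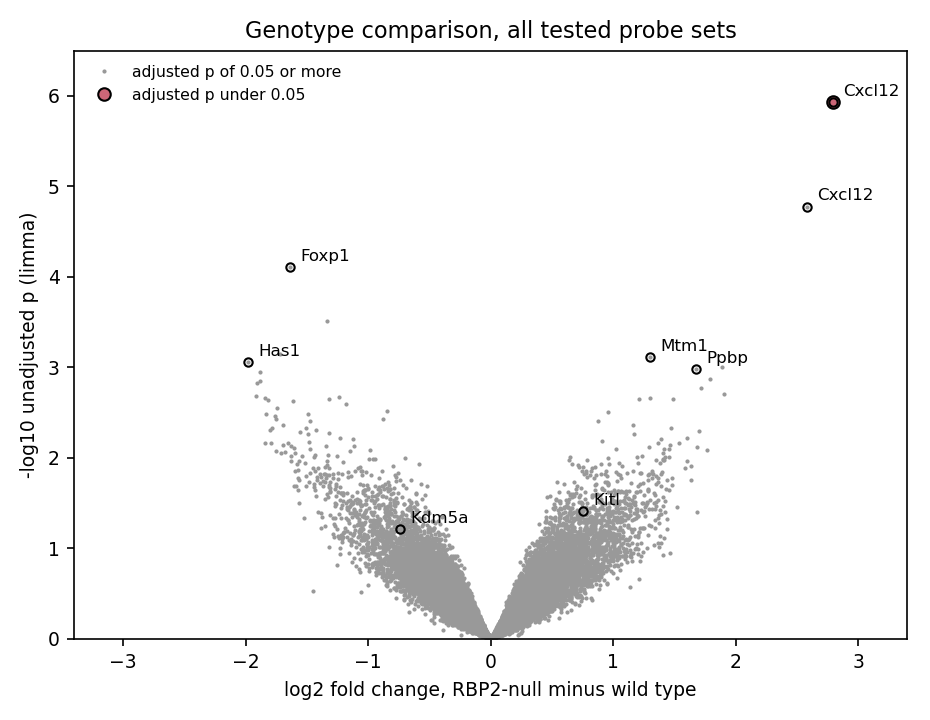
Each point is 1 of the 27022 probe sets, with the log2 fold change of RBP2-null over wild type on the horizontal axis and the negative log10 of the unadjusted limma p on the vertical axis. The filled circle is the Cxcl12 probe set with a log2 fold change of 2.79, the only one past the threshold. Open circles mark labelled probe sets, among them another Cxcl12 probe set and some other named genes.

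Kdm5a, the targeted gene, had a log2 fold change of -0.74 on its brightest probe set, with a standard error of 0.34 and a 95% interval from -1.53 to 0.045, and did not pass the threshold. The normalized log2 signal of this probe set was 6.72 and 7.65 in the wild-type lines and 6.40 and 6.49 in the RBP2-null lines. A dimmer Kdm5a probe set had a log2 fold change of -1.24 with a standard error of 0.41, and 3 further kept probe sets had values of -0.25, 0.24 and 0.15. The part of Kdm5a that was deleted is not given in the sources used here, so a probe set outside it would not check the labels. Without wild-type replicate 2 the value for the brightest probe set was -0.28, and without wild-type replicate 1 it was -1.20. Among the related demethylases, the log2 fold change was -0.0063 for Kdm5b, -0.19 for Kdm5c and 0.12 for the Y-linked Kdm5d, with standard errors of 0.23, 0.26 and 0.77. For Kdm5b and Kdm5d the sign turned with median-centred arrays, at 0.13 and -0.16. Without scaling they had 0.090 and -0.20 relative to the median shift of 0.39 over all genes, so the sign of Kdm5d there depends on subtracting that shift. With wild-type replicate 1 left out the values were 0.16, 0.048 and -0.95, and over all 4 arrays a dimmer probe set of each lay on the other side of 0 from its brightest one, with 0.58, 0.19 and -0.23.

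**Figure D2:**
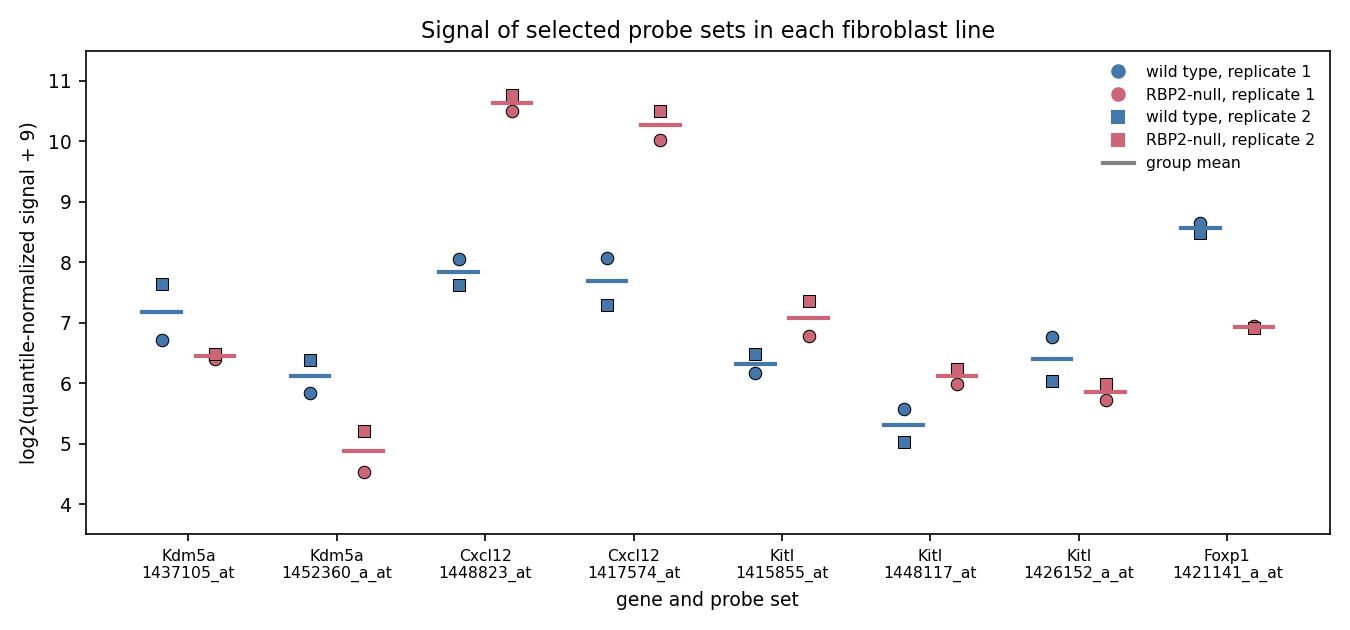
Each symbol is the log2 of normalized signal plus 9 in 1 fibroblast line, with wild type and RBP2-null in different colours, circles for replicate 1, squares for replicate 2 and bars for the mean of 2 lines. For the brightest Cxcl12 probe set the means are 7.84 and 10.64, while the Kitl probe sets differ in direction, with log2 fold changes of 0.76, 0.81 and -0.55.

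Kitl, the ligand of the Kit receptor and a growth factor of stem cells, had kept probe sets that differed in direction. The brightest had a log2 fold change of 0.76 with a standard error of 0.31, or 0.47 without RBP2-null replicate 2, and the dimmest had 0.81 with a standard error of 0.36. The remaining Kitl probe set had -0.55 with a standard error of 0.35. None of the Kitl probe sets passed the threshold, and the limma adjusted p of the brightest was 1.00.

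No other gene passed, and the following are values for the genes with the smallest unadjusted p and at least a 2-fold difference. On the side of higher signal in RBP2-null cells they were Mtm1, a phosphoinositide phosphatase, with a log2 fold change of 1.30 and a standard error of 0.25, and Ppbp, another chemokine, with 1.67 and 0.34. Tmem120b and Taok2 had log2 fold changes of 1.79 and 1.70, and Mgst3, a glutathione transferase, had 1.21 on its brightest probe set and -0.21 on another. For other genes the probe set with the small p was not the brightest. Rhbdd2, Alg6 and Mynn had 1.89, 1.47 and 1.17 on it, against 0.58, 0.20 and 0.47 on their brightest ones, and other Mynn probe sets had -0.25 and -0.16. Ptdss2, a phosphatidylserine synthase, had 1.49, against -0.24 on its brightest probe set. Emp1 had 1.90 and Hadh 1.16 on dimmer probe sets, against -0.060 and -0.18 on their brightest ones. On the side of lower signal, the transcription factor Foxp1 had a log2 fold change of -1.64 with a standard error of 0.23 on 1 of its probe sets and an adjusted p of 0.696. Other Foxp1 probe sets had values of -1.34, -0.85, -0.70, -0.47 and -0.18, and the brightest had 0.47. Has1, a hyaluronan synthase, had -1.98 with a standard error of 0.39, and the Myc family member Mycn had -1.88 with a standard error of 0.39 on its brightest probe set and 0.35 on another. Prdx2, a peroxiredoxin, had -1.72 on a dimmer probe set and 0.065 on its brightest one. Bcl2l14, Slc1a5, Igll1, Gm16499 and Cfap221 had -1.84, -1.32, -1.61, -1.49 and -1.83. Cplx2 had -1.18 on its brightest probe set and 1.25 on another. Epb41l2 and Ttc7 had -1.76 and -1.48, against -0.070 and -0.49 on their brightest probe sets, and another Epb41l2 probe set had 0.20. Some of these values rest on a group mean of normalized signal below the pseudocount of 9. In wild type it was 6.75 for Taok2 and 8.16 for Emp1. In RBP2-null cells it was 8.26, 6.74, 6.3 and 7.14 for Has1, Bcl2l14, Cfap221 and Epb41l2. Of the 52 named genes with at least 2 kept probe sets, 31 had probe sets that differed in direction.

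Of the 31 gene lists tested, 0 passed the threshold with camera, with 3 at an unadjusted p under 0.05, and 0 passed with an estimated correlation or with fry. The smallest adjusted p was 0.217 with camera, 0.975 with an estimated correlation and 0.991 with fry. Camera with an estimated correlation draws on the residual degrees of freedom, 2 with all 4 arrays and fewer with an array left out. It could therefore hardly pass any list, here or in the settings below, and cannot decide whether a list shift is real. For p53 targets the unadjusted camera p was 0.0106. It was 0.103 with an estimated correlation, although that correlation, -0.0065, was below the preset 0.01. Adjusted over the list alone, 3 lists had a member past the threshold, which was Cxcl12 in the chemokine list and among the neighbours of Kdm5a, and Klf1 among erythroid markers. That adjustment does not cover the number of lists, and Klf1 did not pass over all probe sets. With arrays centred on their medians 5 lists passed, without scaling 5 passed, and without wild-type replicate 1 there were 4. With an estimated correlation in the same 3 settings 0 lists passed, and the smallest adjusted p was 0.984, 0.990 and 0.982. Values of single genes depended on single arrays. Of the 109 named genes, 62 moved nearer to 0 by over 1.5 times, or past it, with at least 1 of the 4 arrays left out, of which 11 changed sign. By array there were 40 without wild-type replicate 1, 6 without wild-type replicate 2, 22 without RBP2-null replicate 1 and 16 without RBP2-null replicate 2. For list members among them, the value nearest to 0 or past it is given beside the gene with the array left out, and so is the kept probe set farthest on the other side of 0 where a gene had one.

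Targets of p53, the tumour suppressor activated by DNA damage, had estimates above 0 for 19 of 27 measured members and below 0 for 8, with a median of 0.092 and a camera adjusted p of 0.217. No p53 target passed the threshold, and the list had an adjusted p of 0.975 with an estimated correlation. Fas, a death receptor, had a log2 fold change of 1.58 with a standard error of 0.51, and Perp, Trp53inp1 and Eda2r had 0.84, 0.79 and 0.57. Without wild-type replicate 1 Fas had 1.00 and Trp53inp1 0.10, and a dimmer Trp53inp1 probe set had -0.47. The p53 list passed the threshold with an adjusted p of 0.0166 without scaling and 0.0204 with median-centred arrays, and had an adjusted p of 0.990 and 0.984 there with an estimated correlation.

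Macrophage and other leukocyte markers had estimates below 0 for 10 of 12 measured members and above 0 for 2, with a median of -0.28, a camera adjusted p of 0.217 and an adjusted p of 0.975 with an estimated correlation. No member passed the threshold. Fcgr2b, an inhibitory antibody receptor, had a log2 fold change of -0.61 with a standard error of 0.25, and Fcer1g, Tyrobp and Csf1r had -0.58, -0.54 and -0.28. Fcer1g and Tyrobp had 0.19 and -0.26 with wild-type replicate 1 left out, and a dimmer Csf1r probe set had 0.43. This list passed with an adjusted p of 0.0235 without scaling and 0.0142 with median-centred arrays, where the adjusted p was 0.990 and 0.984 with an estimated correlation.

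Chemokines, cytokines and secreted growth factors had 23 of 37 estimates above 0 and 14 below, with a median of 0.029 and a camera adjusted p of 0.378, or an adjusted p of 0.975 with an estimated correlation. Of these genes 1, Cxcl12, passed the threshold and 36 did not. Cxcl5, a neutrophil attractant, had a log2 fold change of 1.35 with a standard error of 0.52, or 0.52 without wild-type replicate 1, and the growth factor Ereg had 0.50 with a standard error of 0.21.

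Extracellular matrix genes had a median log2 fold change of -0.13 over 47 members and a camera adjusted p of 0.378, or 0.975 with an estimated correlation, and 0 members passed. Without scaling the direction of this list turned, with an adjusted p of 0.575, and without wild-type replicate 1 it passed with an adjusted p of 0.00363, or 0.982 with an estimated correlation. Elastin (Eln) and Fbln1 had log2 fold changes of -0.77 and -0.57, while Efemp1 and Dcn had 1.41 and 0.71. Leaving out wild-type replicate 1 gave -0.43 for Eln, 0.52 for Efemp1 and 0.27 for Dcn, leaving out RBP2-null replicate 2 gave -0.26 for Fbln1, and a dimmer Fbln1 probe set had 0.34. Genes of the unfolded protein and heat shock responses had a median of -0.053 over 27 members and an adjusted p of 0.378, or 0.975 with an estimated correlation, and the direction turned without scaling, with an adjusted p of 0.722. Trib3, Asns, Pdia6 and Herpud1 had -0.40, -0.37, -0.34 and -0.32. Pdia6 had -0.15 without RBP2-null replicate 1 and Herpud1 -0.097 without RBP2-null replicate 2. Genes of the mitochondrial ribosome and of mitochondrial maintenance, the latter with roles in fusion, DNA replication and transcription, had a median of 0.043 over 52 members and an adjusted p of 0.378, or 0.975 with an estimated correlation, and the list passed with median-centred arrays, with an adjusted p of 0.0142, or 0.984 with an estimated correlation. Mrps9, Mrpl45, Mrpl13 and Mrpl40 had 0.79, 0.48, 0.42 and -0.40. Mrps9 and Mrpl45 had 0.13 and 0.31 without wild-type replicate 1, Mrpl13 and Mrpl40 had 0.18 and -0.23 without RBP2-null replicate 1, and a dimmer Mrps9 probe set had -0.24.

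The chromatin and cell cycle lists each had a camera adjusted p of 0.953, no member past the threshold and, at that p, no direction to report. Among the KDM5 family and other H3K4 enzymes, the methyltransferase Setd1b had a log2 fold change of 0.28 and the demethylases Kdm1a and Kdm1b had 0.26 and 0.27. Setd1b and Kdm1a had -0.061 and 0.097 without wild-type replicate 1, Kdm1b had 0.023 without wild-type replicate 2, and a dimmer Setd1b probe set had -0.20. Among other lysine demethylases and Polycomb genes, Kdm4b had 0.99 and Cbx7 had 0.73, against 0.057 without wild-type replicate 1 and 0.37 without wild-type replicate 2. Of the Hox genes, which pattern the body axis, Hoxa13 and Hoxd3 had -0.72 and -0.74, while Hoxd11 and Hoxd13 had 0.94 and 0.62. Hoxd11 and Hoxd13 had 0.26 and -0.10 without wild-type replicate 1, Hoxd3 had -0.24 without RBP2-null replicate 2, and a dimmer Hoxd13 probe set had -0.15. Of the regulators in the RB and E2F pathway, which controls entry into the cell cycle, the CDK inhibitor Cdkn2c had -0.34, Ccne2 had 0.32, Cdk4 had -0.18 and E2f5 had -1.45 with a standard error of 1.29. Cdkn2c, Ccne2 and E2f5 had -0.062, 0.057 and 0.65 without RBP2-null replicate 1, and dimmer probe sets of E2f5 and Cdk4 had 0.53 and 0.10. The S phase genes Tyms and Chaf1b had -0.92 and -0.42, and the mitosis genes Pttg1 and Tpx2 had 0.59 and -0.56. Tyms had -0.13 without RBP2-null replicate 2, Pttg1 and Tpx2 had 0.27 and -0.19 without wild-type replicate 1, and dimmer probe sets of these mitosis genes had -0.22 and 0.14. Without wild-type replicate 1 the S phase and mitosis lists passed, both with an adjusted p of 0.0392, which was 0.982 for both with an estimated correlation.

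The remaining lists of metabolism, translation and stress, with that of interferon-stimulated genes, had 0 members past the threshold and a camera adjusted p of 0.953, except that of housekeeping controls, which had 0.633. In oxidative phosphorylation, Atp5l had a log2 fold change of 0.39 and Atp5a1 had -0.44, and the list passed with an adjusted p of 0.0142 with median-centred arrays and 0.00981 without scaling, or 0.984 and 0.990 with an estimated correlation. Atp5l had 0.21 without RBP2-null replicate 1, Atp5a1 had -0.13 without wild-type replicate 1, and a dimmer Atp5a1 probe set had 0.40. Of the cytosolic ribosomal proteins, Rps15 had -0.24 and Rps25 had 0.34, or 0.030 without RBP2-null replicate 1, and the list passed with an adjusted p of 0.00981 without scaling, or 0.990 with an estimated correlation. In glycolysis and hypoxia, Egln1 had -0.38 and the glucose transporter Slc2a1 had 0.32, and in cholesterol synthesis, Dhcr7 had -0.38 and Fdps had -0.27. Slc2a1 had 0.14 without RBP2-null replicate 2 and Dhcr7 -0.24 without wild-type replicate 1, and dimmer probe sets of Egln1 and Slc2a1 had 0.54 and -0.086. The oxidative stress genes Mt1 and Gpx3 had 0.55 and -0.61, against 0.13 without RBP2-null replicate 2 and -0.049 without wild-type replicate 1. Of the interferon-stimulated genes, the antiviral enzyme Oas1a had -1.33 and Parp9 had 0.74. The housekeeping genes Hprt and Tbp had -0.32 and 0.28, against -0.088 without RBP2-null replicate 2 and 0.11 without wild-type replicate 1.

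Markers of other cell types and lineages were fixed as lists because cultures of embryonic cells can be mixed. Apart from the macrophage list above, the lists of this kind that could be tested, with those of matrix proteases and imprinted genes, had a camera adjusted p of 0.953 except germline and pluripotency genes, with 0.454. Of the smooth muscle genes, Myh11 had a log2 fold change of 1.34 and Tpm2 had -0.46, or -0.15 without wild-type replicate 1, and the list passed without wild-type replicate 1 with an adjusted p of 0.00462, or 0.982 with an estimated correlation. The skeletal muscle genes Chrng and Ckm had -1.07 and 0.70, and the adipocyte genes Dgat2 and Cebpa had -0.56 and 0.71. Dgat2 had -0.20 without RBP2-null replicate 1 and 0.27 on a dimmer probe set, and Cebpa had 0.18 without wild-type replicate 1. The cartilage genes Matn3 and Col9a1, from the osteoblast and chondrocyte list, had 0.78 and -1.02, against 0.19 without wild-type replicate 1 and 0.093 without RBP2-null replicate 1. The endothelial markers Sox17 and Mmrn2 had -0.92 and -0.56, against -0.25 without wild-type replicate 1 and -0.28 without RBP2-null replicate 2. Of the epithelial markers, Pkp1 had 1.42, and of the neural markers, Prph had -0.81 and Tubb3 had 0.84. Prph had -0.43 without RBP2-null replicate 2 and 0.034 on a dimmer probe set. The matrix proteases Htra1 and Adamts4 had -0.44 and 0.57, against -0.17 and -0.16 without wild-type replicate 1. Of the germline and pluripotency genes, Tuba3b and Utf1 had -0.94 and -0.68, against -0.37 without wild-type replicate 1 and -0.063 without RBP2-null replicate 1, and the list passed with an adjusted p of 0.0166 without scaling and 0.0204 with median-centred arrays, or 0.990 and 0.984 with an estimated correlation. Slc22a18, an imprinted gene, had 0.86, or 0.55 without RBP2-null replicate 1. Of the erythroid markers 4 were measured, too few for the list test, with -1.32 for Klf1, -1.12 for Gata1, 0.99 for Hba-a1 and 1.03 for Slc4a1. The limma adjusted p of Klf1 was 0.0215 over the list alone and 0.9998 over all probe sets. Gata1 had -0.35 without RBP2-null replicate 1, and Hba-a1 and Slc4a1 had 0.50 and 0.23 without wild-type replicate 1.

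The 80 measured genes nearest Kdm5a in the order of assembly GRCm38.p6 were tested because a targeted locus carries its neighbours with it. The camera adjusted p of this list was 0.953, and fry gave an adjusted p of 0.991 for a shift in 1 direction and 0.211 for changes in either direction. Cxcl12 was 1 of these 80 genes, the 22nd measured gene from Kdm5a. Zfp637, Zfp239 and Eno2 had log2 fold changes of 0.81, -0.76 and -0.72, and Zfp637 had 0.42 without wild-type replicate 1.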

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

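The fit with the sex of each line as a term, and the estimated correlation under other settings, were chosen only after the data were seen. The count of probe sets past the threshold, 1 in the comparison as reported, was 2 with median-centred arrays, with 2 higher, and 0 without scaling, without the filter on low values, without the mean-dependent variance and with the sex term, with 0 higher in each. It was 82 at an unadjusted p under 0.01 with a 2-fold difference, 31 higher and 51 lower. With each array left out in turn, it ranged from 0 to 42, with 0 to 39 higher and 0 to 3 lower, and the lone line of a genotype was then assumed to vary like the other genotype. The log2 fold change of Cxcl12 was 2.79 without the filter, where 45037 probe sets were tested, and the adjusted p was 0.115. It was also 2.79 without the mean-dependent variance, with an adjusted p of 1, and with the sex term, with 0.0703. Without scaling it was 2.88 relative to the median shift of 0.39 over all genes, with an adjusted p of 0.484. Over the arrays left out, Cxcl12 ranged from 2.58 to 3.01. Its adjusted p over all alternatives ran from 1.13e-18, with the replicate block whose limit is given below, to 1. The cause of these differences was not tested.

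The count of gene lists past the threshold was 5 with median-centred arrays, with a smallest adjusted p of 0.0142, and 5 without scaling, with 0.00981. It ranged from 0 to 4 with arrays left out, with 4 for wild-type replicate 1, and was 0 in these 3 settings with an estimated correlation. That version of the list test could hardly pass any list, given its few residual degrees of freedom. Kdm5b turned to 0.13 and Kdm5d to -0.16 with median-centred arrays, and they had 0.090 and -0.20 without scaling, relative to the same median shift of 0.39. Without scaling the extracellular matrix list turned with an adjusted p of 0.575 and the unfolded protein list with an adjusted p of 0.722. With arrays left out, the matrix list had an adjusted p from 0.00363 to 0.884 and turned without wild-type replicate 2. Log2 fold changes that turned ranged from -0.16 to 1.31 for Adamts4, -2.13 to 0.093 for Col9a1, -3.54 to 0.65 for E2f5, -1.35 to 0.19 for Fcer1g, -0.10 to 1.34 for Hoxd13, -0.061 to 0.63 for Setd1b, -0.17 to 0.16 for Kdm5b, -0.43 to 0.048 for Kdm5c and -0.95 to 1.19 for Kdm5d. For Uty they ranged from -2.25 to 1.32 and for Xist from -2.63 to 1.84. The cause was not tested. Direction and side of the threshold were kept in 1221 values of single genes under other alternatives and 411 with an array left out. The same label was given to 451 and 119 values of gene lists. For lists, direction was compared only where the unadjusted camera p was small in the comparison as reported, and otherwise only the side of the threshold was. Changes of dim probe sets are understated, as 9 units were added to each signal and the median deposited signal was 21.5 to 43.7.

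With the replicate number as a block, 49 probe sets passed, 26 higher and 23 lower, and Cxcl12 had an adjusted p of 1.13e-18. That fit had 69.4 prior degrees of freedom, against 6.46 in the comparison as reported. Its p-values rest almost wholly on the variance pooled over probe sets, and hardly on the spread of each probe set. The block also moved 11 named genes past the threshold, among them Foxp1, Mtm1 and Efemp1. The deviations of same-numbered arrays from their genotype means had a correlation of 0.113 across probe sets. With 2 arrays per genotype the crossed value, -0.113, follows from it and gives no reference. The split by replicate number had 2541 probe sets at an unadjusted limma p under 0.05, against 805 for genotype. In that split 266 genes had at least 2 probe sets that differed the same way, against 16 for genotype. The labels name no litter, batch or day for the numbers, and the array names run in the order wild type 1, RBP2-null 1, wild type 2, RBP2-null 2. Whether same-numbered lines were handled together is therefore open, and the numbers were not taken as pairs.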

Other observations

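The values and tests here were chosen only after the results were seen, except the list of Y-linked genes with Xist and the tests of brightness and of sex for the immediate-early genes. Lines numbered 2 differed from lines numbered 1 in both genotypes. Fos, an immediate-early transcription factor switched on within minutes of serum or stress, was higher by 3.24 (log2) in the lines numbered 2, with a standard error of 0.18 and a limma adjusted p of 0.00174, by 3.03 in wild type and 3.44 in RBP2-null cells. It was the 1 probe set past the threshold in that split, which had 2541 at an unadjusted p under 0.05, against 805 for genotype. At least 2 probe sets differed the same way at that level for 266 genes, against 16 genes for genotype. Other immediate-early genes went both ways, with log2 differences of 2.44, 1.44, 1.34, 1.21 and 0.69 for Fosb, Nr4a1, Jun, Klf4 and Egr1, and -0.55, -0.49 and -0.34 for Nr4a3, Myc and Dusp6. Among measured targets of SRF, MRTF and YAP, the values were -1.72 for Acta1, -1.42 for Ankrd1, -1.06 for Tgm2, -0.82 for Cnn1 and -0.67 for Ccn2, and of the 31 whose values had not been seen 4 were above 0.

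Xist, the RNA of the inactive X chromosome, had a deposited signal of 426.7 and 4.4 in wild-type replicates 1 and 2 and 1 and 1008 in RBP2-null replicates 1 and 2 on 1 probe set. The Y-linked Eif2s3y had 0.7, 129.3, 108.5 and 4.6 in the same order on 1 probe set. By these probe sets wild-type replicate 1 and RBP2-null replicate 2 read as female and the other lines as male, 1 of each sex per genotype. Not every Y-linked probe set followed, with 2.4, 111.1, 106.2 and 55 in the same order on 1 Uty probe set and 0.3, 12.8, 1.9 and 7.7 on a dimmer one of Eif2s3y. The list of Y-linked genes and Xist gave a camera adjusted p of 0.953 between genotypes, with -0.47 for Uty and -0.39 for Xist. That test could hardly show a sex difference, since the list joins genes that move in opposite ways with sex. Each genotype also held 1 line read as female and 1 as male. A dimmer Uty probe set had 1.14, and the sign turned to 1.32 for Uty without RBP2-null replicate 2 and 1.84 for Xist without wild-type replicate 1.

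Cxcl12 signal was higher in both RBP2-null lines. Array brightness is argued against, since without scaling the dimmer RBP2-null replicate 1 exceeded the brighter wild-type replicate 2 by at least 5.65 times on both kept probe sets. Sex is argued against by within-sex differences in log2 signal, the smallest of which was 2.45. The 4 arrays allow 3 splits into 2 and 2, all 3 with at least as many probe sets past the threshold, which is too few for a share under 0.05, and the real split had 1 where the highest other had 4, that of sex, whose calls include 2 probe sets of Xist. Genotype may account for the Cxcl12 difference, as a hypothesis that 2 lines per genotype leave open beside other differences between the lines. Cxcl12 also had the smallest p of the 17 top genes near Kdm5a given below. Sequence variants linked to the targeted locus would travel with genotype, so for Cxcl12 they cannot be told apart from loss of RBP2.

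Genes with small genotype p-values lay near Kdm5a, with 17 of the top 200 among the 300 measured genes around it, where 4.59 would fall by chance, 7 higher and 10 lower. A gain or loss of the region is argued against by a median log2 fold change there of 0.017 (95% bootstrap interval -0.0298 to 0.0465), inside the bound of 0.32. Chance placement cannot be told apart, because rotating the gene order gave a one-sided p of 0.00566 at this window and rank, the lowest of 12 settings, of which 5 were under 0.05 and the highest was 0.436. Sequence variants linked to the targeted locus, of another strain, may lie behind the excess, with 17 near Kdm5a against 7 of 362 genes on the rest of the chromosome (one-sided Fisher's exact p = 0.00923, at that same setting), and 0 of 24 settings in the other splits under 0.05. They also cannot be told apart from chance, since the labels give no strain and the nearest 40 genes on each side held 2 of the top 200 where 1.22 would fall by chance, and 6 of the top 400 where 2.45 would (one-sided rotation p of 0.0516).

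Of the 32 measured immediate-early genes whose values had not been seen, 20 were above 0 in the difference of lines numbered 2 from lines numbered 1, with a median of 0.17 (log2). Brightness cannot be told apart as a cause, because in both genotypes the array numbered 2 was brighter as deposited than the array numbered 1. The largest camera p over 3 scalings was 0.00125. With an estimated correlation the p was 0.160, 0.416 and 0.105, but that test had so few residual degrees of freedom that it could hardly give a small p. Sex is argued against by a median difference in log2 of 0.22 or more (0.218 in wild type and 0.265 in RBP2-null cells) in both genotypes, as same-numbered lines differ in sex. A state of the cultures at harvest, such as density or time since feeding, may account for it, and targets of SRF, MRTF and YAP were lower in the lines numbered 2 with a camera p of 2.36e-11, 0.00229 with median-centred arrays and 0.624 without scaling. With an estimated correlation that p was 0.119, 0.526 and 0.676, from a test that could hardly give a small p here. As the camera p depended on the scaling, this explanation cannot be told apart from other differences between the lines.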
